A study of Mus musculus with 12 samples.

How the data were processed

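Sensory neurons of mice were labelled with the RiboTag system, in which a Cre recombinase expressed under the advillin promoter adds an HA tag to the ribosomal protein RPL22, so that ribosomes of these cells and the RNA bound to them can be precipitated. The sciatic nerve was crushed, and lumbar dorsal root ganglia were taken 3 days later from the injured side and from an uninjured (naive) side. Ganglia of 4 mice were pooled for each replicate. RNA from the precipitate (IP) and from the ganglion homogenate before precipitation (input) was made into QuantSeq REV libraries, which read the 3′ ends of polyadenylated RNA. There were 12 libraries in 4 groups of 3: IP naive, IP injured, input naive and input injured.

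The deposited table gives raw counts per genomic interval and library, with no normalization. The submitters' processing notes name bcl2fastq 2.17, STAR and HTSeq, and the genome builds GRCm38 and mm10, without saying which step each served. How the intervals were called and how reads with several alignments were treated is not stated. Of the intervals, 92.7% were 25 bp wide and the widest was 148 bp, and each carried the name of a repeat family or NA. Intervals are called sites below. Starts and ends are printed as deposited, and whether positions were counted from 0 or from 1 is not stated. The table held 178451 lines, of which 20 were damaged and left out, so that 178431 sites were used. A further 17 columns had no name and were not used here. The sites came in 2 blocks sorted by position. Among sites with at least 5000 counts, 1362 in the first block lay within 100 bp of the lower-coordinate end of a gene alone and 15 near the higher-coordinate end alone. In the second block 1371 lay near the higher-coordinate end and 11 near the lower one. The first block was therefore taken as the minus strand (86226 sites) and the second as the plus strand (92205 sites). All 10152 sites whose name held a simple repeat or low complexity, alone or with other families, lay in the second block.

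Sites were tied to genes by position in a RefSeq gene table of GRCm38.p6, the build of the deposited positions. The table gives no strand and no exons, so the strand of a gene was taken from the counts, either from the site within 100 bp of one of its ends (at least 60 counts and 10 times the counts at the other end) or from a strand holding at least 90% of the counts over the gene. Where both readings were possible for a protein-coding gene they gave the same strand in 99.1% of genes. The counts over a gene include those at its ends, so the readings share counts and their agreement does not test the strands. Genes reached up to 200 bp past their annotated 3′ end. A site was tied to a gene when it lay in a single gene on that gene's strand. This held for 70709 sites in 14149 genes, with 79.7% of all counts. Of 34696 genes considered, 19878 received no strand. Sites were sorted into those at an annotated 3′ end, elsewhere in a gene on its strand, in a gene on the opposite or an unresolved strand, and outside genes.

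Total counts per library ranged from 10045178 to 18687123. Sites, repeat families and genes were tested with edgeR 4.0.16 in R 4.3.3. Families were counts summed over the sites with the same family name. Genes were counts summed over the sites tied to a gene that lay outside repeats or at its annotated 3′ end. Other tied sites in repeats were left out of the gene sums. All 12 libraries entered a single quasi-likelihood fit with 1 mean per group, TMM factors and the filterByExpr filter. The two-sided p-values were adjusted by the Benjamini-Hochberg method over all units tested, with a threshold of 0.05. Tested were 46229 sites with 99.0% of the counts, 180 families, and 11436 genes with 74.2% of the counts. The 5 comparisons were injured against naive in IP and in input, IP against input in naive and in injured ganglia, and the difference between the injury effect in IP and that in input (the interaction). Errors after ± are standard errors for log2 fold changes and standard deviations over 3 libraries for shares. Fold changes against a group with 0 counts are lower bounds from a floor of 3 counts over the 3 libraries of that group. Those against 1 to 3 counts are printed with an exact Clopper-Pearson counting interval. Intervals and floors cover counting error only, since reads without molecular identifiers are not independent molecules, and p-values measure only the spread between these pools. Shares of counts were compared by a two-sided exact permutation test, which for 3 against 3 libraries cannot give a p below 0.1.

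The use of alternative sites was tested per gene with diffSpliceDGE of edgeR. This test used sites outside repeats or at an annotated 3′ end, 15915 sites in 5340 genes with more than 1 such site. It asks whether the share of a site in the counts of its gene differs between groups. The 12 gene lists are injury-induced and regeneration-associated genes, nociceptor and sensory receptor, channel and transmitter genes, pan-neuronal genes, markers of satellite glia, Schwann cells and myelin, macrophages and other immune cells, fibroblasts and matrix, endothelium, pericytes and smooth muscle, and erythroid cells, proliferation genes, and transposon silencing and restriction genes. Lists were tested with camera of limma 3.58.1 at a preset correlation of 0.01 and again with the correlation estimated from the data. Classes of repeat elements by age could not be formed, because the table names families and not subfamilies, and the families took their place as sets of sites.

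The groups, the 5 comparisons, the model, the filter, the threshold, the lists and the rule for naming were fixed before the data were examined, as were the alternatives except those named here. Gene sums, the use of sites, lists summed per gene, the fit without both IP libraries numbered 2, the shares without rRNA or without B2, the factors taken from gene sums, and the restriction to annotated 3′ ends were added after the table had been seen. For the 3 main comparisons (both injury comparisons and IP against input in naive ganglia) the rule named the 8 sites with the largest rises and the 8 with the largest falls among those past the threshold, with a mean abundance at or above the median of tested sites and no overlap between the libraries of the groups. The other 2 comparisons gave 3 sites each way. It also named up to 5 families each way, up to 4 members of each list each way, and the 5 most abundant sites. Of the genes it named, 2 are not reported here, although counts of named genes include them. B2, Alu and L1 and further list members were singled out after their values were seen.

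Alternatives were RLE factors, no factors, DESeq2 1.42.0, no filter, a filter of at least 30 counts in 3 libraries, only the groups compared in the fit, a term for the replicate number, each library left out in turn, and for families the sum without the highest site and the sum over sites outside genes. The labels do not say that a replicate number marks the same pool in every group. Deviations of same-numbered libraries from their group means were hardly correlated across sites (0.042, 0.12 and 0.045 between naive and injured IP). These correlations were 0.022, 0.016 and 0.043 between naive and injured input. Between IP and input they were 0.0066, 0.027 and -0.004 in naive and 0.034, 0.019 and -0.027 in injured ganglia. In IP, however, depth and the share of ribosomal RNA each had the same order by number in naive and injured ganglia. In input neither did. A pool or batch shared by number is therefore not excluded, and the main fit holds no term for it. The replicate term was run as an alternative only.

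The pipeline was tested on simulated data in which 200 sites or genes were changed. For injury in IP, the site test recovered 2.99%, 17.9% and 36.4% of changes of 2-fold, 4-fold and 16-fold, among 46229 sites. The gene test recovered 37.3%, 58.2% and 84.8%, among 11436 genes, with 8.4% of its calls false. For the interaction the site test recovered 0%, 5.97% and 28.8%, and the gene test 16.4%, 44.8% and 72.7%.  Of 8 simulated sets of 40 sites raised 2-fold, 8 were called, and of 72 unchanged sets 0 were called. The simulated sites were drawn independently of each other, so false calls of sets from correlated sites were not tested. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 was used for the tables and plots.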

Results

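The 12 libraries measured 3′ ends of RNA from mouse dorsal root ganglia, either bound to tagged ribosomes of sensory neurons (IP) or in the whole ganglion (input). Each of the 4 groups, IP naive, IP injured, input naive and input injured, held 3 libraries, and each library came from ganglia of 4 mice, taken 3 days after a crush of the sciatic nerve. Total counts of naive libraries 1 to 3 were 16843737, 12860794 and 18527515 in IP and 10045178, 14053174 and 12610260 in input. Injured libraries held 16740279, 12500443 and 18687123 counts in IP and 10412956, 13656228 and 13839648 in input. Ribosomal RNA took between 8.21% and 15.1% of the counts of a library. Among the 5 most abundant sites were 2 in ribosomal RNA on chromosome 17 (39847334 to 39847359 and 39847500 to 39847525, GRCm38). The others lay at the annotated 3′ ends of Tuba1a (chromosome 15, 98949853 to 98949878), which encodes an alpha tubulin, Uchl1 (chromosome 5, 66687174 to 66687199), a ubiquitin hydrolase abundant in neurons, and Actg1 (chromosome 11, 120345709 to 120345734), a cytoplasmic actin.

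The first question was which RNAs on the ribosomes of sensory neurons change after nerve injury. Atf3, a transcription factor induced by axon injury, rose 41.8-fold in IP (log2 5.38 ± 0.33, adjusted p = 6.23e-08, 3 against 3 libraries, edgeR quasi-likelihood). Gal, which encodes the neuropeptide galanin, rose by 4.96 ± 0.36 on the log2 scale (adjusted p = 4.26e-06), and Sox11, a transcription factor of growing axons, by 2.97 ± 0.25 (adjusted p = 6.52e-07). The growth cone protein gene Gap43 rose by 1.37 ± 0.11 (adjusted p = 8.13e-08), Jun by 1.33 ± 0.14 (adjusted p = 4.16e-06) and the cell cycle inhibitor gene Cdkn1a by 2.38 ± 0.13 (adjusted p = 5.26e-10). Csf1, a growth factor for macrophages and microglia, rose by 2.95 ± 0.31 (adjusted p = 2.48e-06), and Sema6a, a guidance molecule, by 3.45 ± 0.25 (adjusted p = 2.92e-08). These genes except Atf3 were singled out from the regeneration list after their values were seen. All 8 passed the threshold with any 1 library left out. Sprr1a rose 90.2-fold (log2 6.50 ± 1.09, adjusted p = 0.0236), Gpr151 114-fold (6.84 ± 1.22, adjusted p = 0.0271) and the cholecystokinin receptor gene Cckbr 120-fold (6.91 ± 1.20, adjusted p = 0.00692), but Cckbr lost its call without IP naive 1 (adjusted p = 0.0501), Sprr1a kept it only without IP naive 2 and Gpr151 only without IP naive 1 (highest adjusted p = 0.132 and 0.0971). Glul, the glutamine synthetase gene that marks satellite glia, rose 1.85-fold (log2 0.89 ± 0.11, adjusted p = 3.92e-05) and kept its call without any 1 library. Whether it rose in neurons or in glial RNA carried into the IP was not tested. Map1b, Bex1 and Socs3, also on the regeneration list, were not past the threshold (log2 0.05, -0.26 and -0.07, adjusted p = 0.97, 0.92 and 1). In all, 144 genes rose and 26 fell by edgeR, and the 170 became 99 without IP naive 1 and 104 without IP injury 3. Of the 10 genes named by rule, 6, 3 and 7 lost their call without IP naive 1, 2 and 3, and 5, 6 and 7 without IP injury 1, 2 and 3.

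Falls in IP were fewer than rises. Htr3a, a serotonin-gated ion channel gene, fell by 0.95 ± 0.21 on the log2 scale (adjusted p = 0.0156), and Scn10a, the gene of the nociceptor sodium channel Nav1.8, fell by 0.58 ± 0.14 (adjusted p = 0.0302). Cntnap2, which anchors potassium channels along axons, fell by 0.75 ± 0.18 (adjusted p = 0.0318). The Cntnap2 call was lost without any 1 of the 6 libraries (highest adjusted p = 0.131). The Scn10a call was kept only without IP naive 2 (highest adjusted p = 0.177), and the Htr3a call was lost without IP naive 3, IP injury 2 and IP injury 3 (adjusted p = 0.068, 0.0823 and 0.0971). The axonal gene Stmn2 rose by 0.44 ± 0.10 (adjusted p = 0.0195), a call kept only without IP injury 2 (highest adjusted p = 0.134). C1qc, a complement gene of macrophages, rose by 2.40 ± 0.52 (adjusted p = 0.0162) and was not past the threshold without IP naive 1, IP naive 3, IP injury 2 and IP injury 3 (adjusted p = 0.112, 0.0685, 0.0503 and 0.172). Marker genes of cells without the tag kept a median of 0.0829 (IP naive 1) to 0.22 (IP injury 3) of their input level in the IP libraries. Macrophage markers had a median log2 change of 0.938 after injury in input. The rise of C1qc may thus be macrophage RNA carried into the IP, which was not tested.

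Among the 44 tested regeneration genes, 30 rose and 0 fell in IP (38 and 0 adjusted over the list alone), with a median log2 change of 2.33, and the list passed with an estimated correlation (camera, adjusted p = 0.000604). With 1 library left out between 23 and 31 of them were called. Of 42 nociceptor genes, 0 rose and 2 fell (0 and 7 adjusted over the list alone; median -0.322; adjusted p = 0.00676 with an estimated correlation). In the planned test on sites, at the preset correlation, the nociceptor and regeneration lists both passed (camera, adjusted p = 0.00177 and 7.47e-47). With an estimated correlation on sites the nociceptor list did not pass (adjusted p = 0.242), whereas the regeneration list did (adjusted p = 0.000312). The count of falls in the nociceptor list was 0 without IP naive 3 and 0 without IP injury 3, and 1 without IP injury 1 or IP injury 2. Of 31 pan-neuronal genes 1 rose and 1 fell (3 and 5 adjusted over the list alone; adjusted p = 0.55 with an estimated correlation). The macrophage list passed at the preset correlation (1 of 21 called, median 0.599, adjusted p = 0.0241) and not with an estimated correlation (adjusted p = 0.55). Satellite glia markers gave 1 rise of 19 (Glul; list adjusted p = 0.751 with an estimated correlation). Schwann cell, fibroblast, endothelial, pericyte, erythroid, proliferation and transposon silencing genes gave 0 calls by edgeR (adjusted over the list alone, 1 rise in the endothelial list and 0 in the others), and their adjusted p with an estimated correlation was 0.751, 0.88, 0.751, 0.55, 0.831, 0.55 and 0.751.

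At single 3′ end sites the largest rises in IP started from naive libraries with 0 counts. A B2 copy in Agbl3, a gene for a carboxypeptidase that trims tubulin tails (chromosome 6, 34784906 to 34784931, GRCm38, 76021 bp upstream of the annotated 3′ end), rose at least 87.8-fold (adjusted p = 0.0107). A B2 copy outside genes on chromosome 2 (103828586 to 103828613) rose at least 69.8-fold (adjusted p = 0.00089) and one within a gene, on the opposite or an unresolved strand (chromosome 15, 84276690 to 84276721), at least 59.2-fold (adjusted p = 0.00129). The Atf3 site at the annotated 3′ end (chromosome 1, 191170312 to 191170337) rose by 5.36 ± 0.36 (adjusted p = 1.75e-05), the Glul site (chromosome 1, 153909627 to 153909660) by 0.87 ± 0.12 (adjusted p = 0.00416), and a Stmn2 site 1167 bp upstream of the 3′ end (chromosome 3, 8560410 to 8560464) by 0.62 ± 0.09 (adjusted p = 0.0068). These 6 sites were called in every fit with 1 library left out. The transcription factor gene Etv1 had the site with the third-largest fall, 3876 bp upstream of its 3′ end (chromosome 12, 38866595 to 38866620; -1.09 ± 0.17, adjusted p = 0.0164). A site at the 3′ end of Nmb, which encodes neuromedin B (chromosome 7, 80902245 to 80902270), fell by 0.62 ± 0.10 (adjusted p = 0.0113). Both falls were lost in some fits (highest adjusted p = 0.111 and 0.117). In all, 145 sites rose and 5 fell. The total of 150 became 66 and 332 without IP naive 1 and 2, and 93, 76 and 91 without IP injury 1, 2 and 3. Of the 19 sites named by rule, 12, 3 and 10 lost their call without IP naive 1, 2 and 3, and 9, 11 and 9 without IP injury 1, 2 and 3.

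The same comparison in input asked how the RNA of the whole ganglion changes. Atf3 rose 67.3-fold in input (log2 6.07 ± 0.35, adjusted p = 8.79e-08) and Npy, which encodes neuropeptide Y, 29.9-fold (4.90 ± 0.76, adjusted p = 0.00911), both called in every fit with 1 library left out. Sprr1a rose 132-fold (adjusted p = 0.0222) and Gpr151 110-fold (adjusted p = 0.0405), with highest adjusted p of 0.0689 and 0.108 when a library was left out. Among genes singled out after their values were seen, Gal rose by 3.96 ± 0.34, Sox11 by 2.71 ± 0.25, Gap43 by 1.32 ± 0.11, Jun by 1.11 ± 0.14 and Cdkn1a by 1.57 ± 0.13 on the log2 scale. The potassium channel gene Kcna2 fell by 0.74 ± 0.18 (adjusted p = 0.0488), Htr3a by 0.90 ± 0.21 (adjusted p = 0.0278), and Runx1, a transcription factor of nociceptors, by 0.75 ± 0.17 (adjusted p = 0.0218). Tubb3, a neuronal tubulin gene, rose by 0.51 ± 0.10 (adjusted p = 0.009), whereas Rbfox3, which encodes the neuronal splicing factor NeuN, and the neurofilament gene Nefl fell by 0.52 ± 0.13 (adjusted p = 0.0444) and 0.35 ± 0.09 (adjusted p = 0.0442). Highest adjusted p with 1 library left out was 0.206 for Kcna2, 0.187 for Htr3a, 0.0937 for Runx1, 0.0915 for Tubb3, 0.163 for Rbfox3 and 0.23 for Nefl. In all, 103 genes rose and 40 fell by edgeR. Of the 12 genes named by rule, 7, 5 and 5 lost their call without input naive 1, 2 and 3, and 8, 9 and 5 without input injury 1, 2 and 3.

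Of the regeneration genes, 28 rose and 0 fell in input (33 and 1 adjusted over the list alone; median 2.02; adjusted p = 0.00137 with an estimated correlation), and between 22 and 26 were called with 1 library left out. Of the nociceptor genes 0 rose and 5 fell (0 and 10 adjusted over the list alone; median -0.428; adjusted p = 0.00375 with an estimated correlation). In the planned test on sites, at the preset correlation, the nociceptor and regeneration lists both passed (camera, adjusted p = 1.14e-05 and 6.77e-24). With an estimated correlation on sites the nociceptor list did not pass (adjusted p = 0.0738), whereas the regeneration list did (adjusted p = 0.00349). The count of falls in the nociceptor list was 2, 1 and 3 without input naive 1, 2 and 3 and 2, 1 and 3 without input injury 1, 2 and 3. Pan-neuronal genes gave 2 rises and 2 falls (4 and 8 adjusted over the list alone; adjusted p = 0.507 with an estimated correlation). Macrophage markers gave 0 calls of 21 with a median of 0.938, and passed at the preset correlation (adjusted p = 0.0434) but not with an estimated correlation (adjusted p = 0.69). Satellite glia, Schwann cell, fibroblast, endothelial, pericyte, erythroid, proliferation and transposon silencing genes gave 0 calls by edgeR (adjusted over the list alone, 1 rise in the satellite glia list and 0 in the others), with adjusted p = 0.985, 0.985, 0.948, 0.69, 0.985, 0.985, 0.507 and 0.69 with an estimated correlation.

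Among single sites in input, the B2 copy in Agbl3 rose at least 236-fold (adjusted p = 0.00845). A B2 copy in Igf2bp2, an RNA-binding protein gene (chromosome 16, 22068819 to 22068844, 94468 bp upstream of the 3′ end), rose at least 205-fold (adjusted p = 0.00845). The sites at the 3′ ends of Csta2, a cysteine protease inhibitor gene (chromosome 16, 36257404 to 36257429), and Lipn, a lipase gene (chromosome 19, 34085904 to 34085929), rose at least 128-fold (adjusted p = 0.0133) and at least 114-fold (adjusted p = 0.0139). The Atf3 site rose by 5.95 ± 0.38 (adjusted p = 2.21e-05). Falls included 3′ end sites of the sodium channel gene Scn1a (chromosome 2, 66270803 to 66270828; -1.68 ± 0.24, adjusted p = 0.00992) and of Nrn1, which encodes the neurite growth protein neuritin (chromosome 13, 36725765 to 36725816; -1.01 ± 0.16, adjusted p = 0.0184). The Etv1 site named for IP fell by 1.08 ± 0.17 (adjusted p = 0.0215). The Atf3, Igf2bp2 and Agbl3 sites were called in every fit with 1 library left out, and those of Csta2, Lipn, Scn1a, Nrn1 and Etv1 were not (highest adjusted p = 0.0622, 0.0529, 0.0537, 0.109 and 0.112). In all, 83 sites rose and 13 fell. The total of 96 became 45, 57 and 58 without input naive 1, 2 and 3, and 49 and 51 without input injury 2 and 3. Of the 20 sites named by rule, 13, 12 and 9 lost their call without input naive 1, 2 and 3, and 9, 15 and 13 without input injury 1, 2 and 3.

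The next comparison set the injury effect in IP against that in input. Atf3, Sprr1a, Gpr151, Gal and 77 further genes rose in both, 81 in all, where 1.3 would be shared if the calls were independent. Htr3a, Scn10a, Nmb and Etv1 were among the 11 genes that fell in both (0.0909 if independent). Input is the homogenate from which the IP is drawn, and both comparisons come from a single fit. Independent calls were therefore not to be expected, and the overlap is no test. Cdkn1a rose by 2.38 in IP and 1.57 in input, a difference of 0.81 that was not past the threshold (adjusted p = 0.603). The difference was 0.47 for Glul (adjusted p = 1), 1.60 for C1qc (adjusted p = 1) and 3.09 for Anxa1 (adjusted p = 1), a gene of the regeneration list that rose in IP (4.51 ± 0.72, adjusted p = 0.00078). Of 221 genes called in either, 219 had the same sign in both. The interaction gave 0 of 11436 genes and 0 of 46229 sites by edgeR, with 369 genes and 2292 sites at an unadjusted p under 0.05 and 13 genes and 77 sites by DESeq2. Without IP naive 2 edgeR gave 2 genes. Across all tested genes, which are not independent replicates, the log2 changes in IP and input had r = 0.276.

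**Figure D1:**
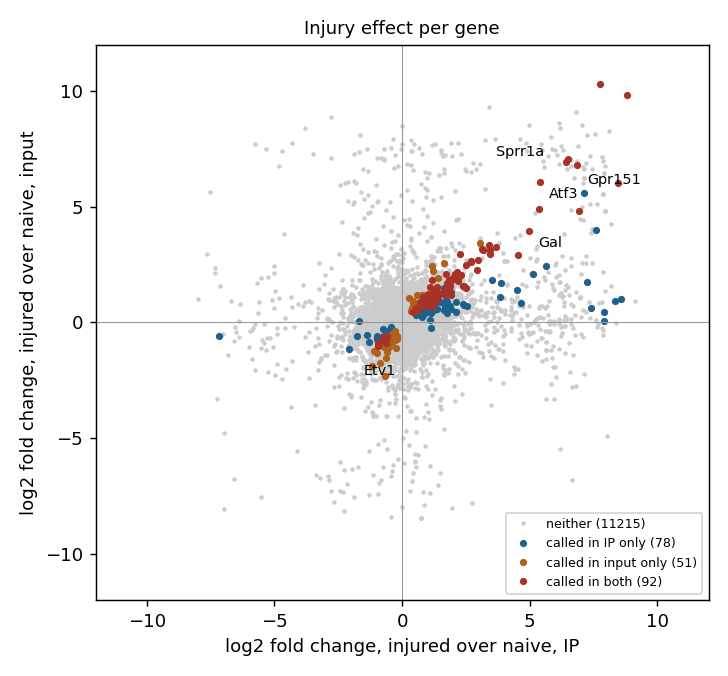
Fitted log2 fold change after injury in IP (x axis) and in input (y axis) for 11436 genes, each point a gene, coloured by whether its adjusted p was under 0.05 in IP, input or both. The 92 genes called in both lie in the upper right (81) or lower left (11).

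The comparison of IP with input in naive ganglia shows which transcripts the tagged ribosomes select. Transcripts of cells other than neurons were lower in IP. Gja1, the connexin gene of satellite glia, was lower by a log2 of -3.44 ± 0.47 (10.9-fold, adjusted p = 7.31e-05, edgeR), Apoe by -2.86 ± 0.40 (7.25-fold, adjusted p = 0.00223) and the glial transcription factor gene Sox10 by -2.77 ± 0.35 (6.84-fold, adjusted p = 3.39e-05). The myelin genes Mag and Gjb1 were lower by -5.01 ± 0.57 (32.1-fold, adjusted p = 9.86e-06) and -5.14 ± 0.98 (35.4-fold, adjusted p = 0.00201). C1qc and C1qa of macrophages were 14.0-fold (adjusted p = 0.000112) and 13.4-fold lower (adjusted p = 0.00754), Mgp and Lum of the matrix 10.8-fold (adjusted p = 1.16e-06) and 9.84-fold lower (adjusted p = 1.39e-05), and Acta2 of smooth muscle 21.4-fold lower (adjusted p = 2.59e-05). Ly6c1 and Cdh5 of endothelium were 10.1-fold and 6.32-fold lower, and the erythroid genes Alas2 and Hbb-bs were lower by -4.08 ± 0.45 and -3.20 ± 0.55 (adjusted p = 6.51e-06 and 0.00977). Neuronal genes were higher in IP by less: Grik1 by 1.03 ± 0.22 (2.05-fold, adjusted p = 0.00526), Syt1 by 0.91 ± 0.17 (adjusted p = 0.00221) and Stmn3 by 0.74 ± 0.14 (adjusted p = 0.00147), each kept in every fit with 1 library left out, and Prph, Syt4 and Ret by 0.75, 0.78 and 0.50, which were not (highest adjusted p = 0.0706, 0.0518 and 0.176).

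In all, 246 genes were higher and 554 lower in IP, and the 800 became 495 and 498 without IP naive 1 and 3. Of the 39 genes named by rule, 12, 6 and 10 lost their call without IP naive 1, 2 and 3, and 10, 7 and 11 without input naive 1, 2 and 3. Without normalization factors 17% of called genes were higher in IP (124 up and 606 down), against 30.8% with TMM factors. All 13 called satellite glia markers of 19 were lower (16 adjusted over the list alone; median -2.25; adjusted p = 0.00666 with an estimated correlation), as were 13 of 20 Schwann cell (15; -2.78; 0.00646), 8 of 21 macrophage (14; -2.79; 0.0442), 9 of 14 fibroblast (13; -3.01; 0.00646), 7 of 15 endothelial (8; -1.87; 0.00646), 2 of 12 pericyte (5; -3.24; 0.0078) and 4 of 4 erythroid markers (4; -3.64; 0.0192). In the planned test on sites, at the preset correlation, each of these lists passed (camera, highest adjusted p = 0.0256, for endothelial markers). With an estimated correlation on sites the adjusted p was 0.0504, 0.0183, 0.0842, 0.0202, 0.0504, 0.0438 and 0.0368 in the same order. The satellite glia, macrophage and endothelial lists did not pass with that correlation. Pan-neuronal genes gave 9 of 31 higher and 0 lower (11 and 1 adjusted over the list alone; median 0.288; adjusted p = 0.0305 with an estimated correlation and 0.0368 on sites). The nociceptor list gave 2 higher of 42, Grik1 and Ret, and passed at the preset correlation (median 0.17, adjusted p = 0.0157) but not with an estimated one (adjusted p = 0.0509). Regeneration genes gave 3 higher, Gap43, Smad1 and Stmn4, and 2 lower, Anxa1 and Cdkn1a (adjusted p = 0.907 with an estimated correlation). Proliferation genes gave 2 lower, Ccnb2 and Cdk1 (adjusted p = 0.213), and silencing genes 0 (adjusted p = 0.882). Macrophage calls dropped to 3 without IP naive 1 or IP naive 3 and to 4 without input naive 3. Endothelial calls dropped to 4 without IP naive 1 or input naive 1 and to 3 without input naive 3, pan-neuronal calls to 5 without IP naive 1, IP naive 3 or input naive 2, and proliferation calls to 0 without IP naive 1 and 1 without each other library but input naive 2. The count of higher regeneration genes was 1 without IP naive 1, IP naive 2 or input naive 1 and 0 without input naive 3, and that of nociceptor genes 1 without IP naive 1, IP naive 3, input naive 1 or input naive 3.

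**Figure D2:**
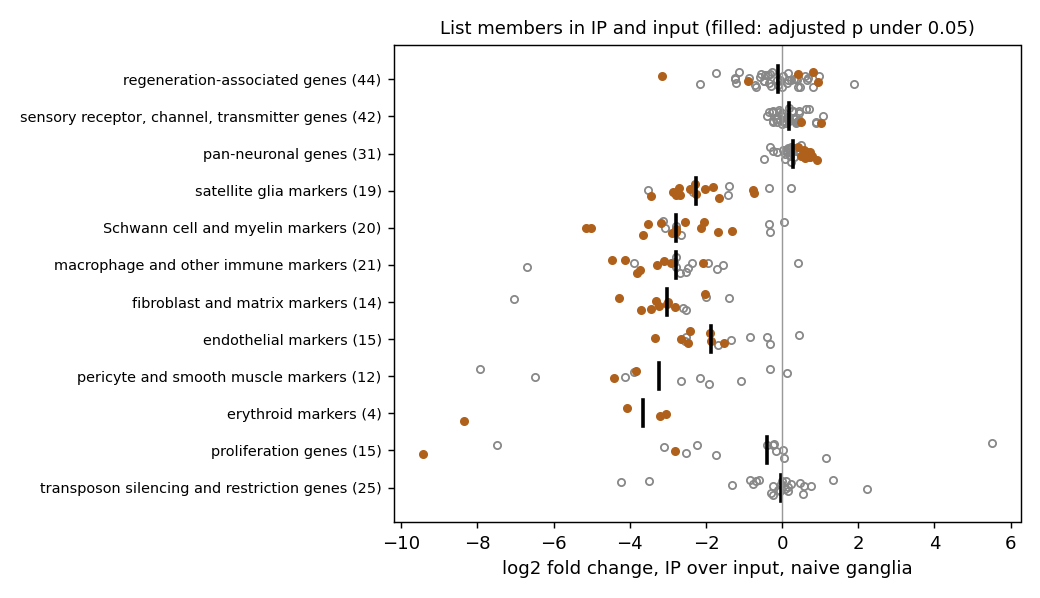
Log2 fold change of IP over input in naive ganglia (x axis) for the members of the 12 gene lists (number of tested genes in brackets), with 1 point per gene, filled when the adjusted p was under 0.05, and the median as a bar. The medians of the 7 lists of other cell types lie between -3.64 and -1.87, and that of pan-neuronal genes at 0.288; fitted values below -8 belong to genes with 0 counts in IP.

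At single sites 795 were higher and 1302 lower in IP from naive ganglia. The Gja1 site at its 3′ end (chromosome 10, 56390390 to 56390415) was lower by a log2 of -3.13 ± 0.48 (adjusted p = 0.00552), the Mgp site (chromosome 6, 136872446 to 136872471) by -3.13 ± 0.30 (adjusted p = 0.000549) and the Alas2 site (chromosome X, 150570579 to 150570604) by -3.78 ± 0.48 (adjusted p = 0.0023). Cd53, a leukocyte membrane protein gene, had 0 counts in IP at a site 1090 bp upstream of its 3′ end (chromosome 3, 106759939 to 106759964), at least 137-fold lower (adjusted p = 0.00677). A site in Zmiz1, a transcriptional coregulator gene, 1810 bp upstream of the 3′ end (chromosome 14, 25664921 to 25664946), had 0 counts in input and was at least 90.6-fold higher (adjusted p = 0.00617). The 3′ end site of Fastkd5, a mitochondrial RNA-processing gene (chromosome 2, 130613856 to 130613881), was higher by 3.66 ± 0.63 (adjusted p = 0.00724). The Schwann cell gene Pllp had 3 counts in IP at its 3′ end site (chromosome 8, 94674901 to 94674926) against 284 in input, a ratio of 0.0097 with a counting interval of 0.00199 to 0.0286 (adjusted p = 0.0123). These 7 sites were called in every fit with 1 library left out. Of the 58 sites named by rule, 28, 4 and 31 lost their call without IP naive 1, 2 and 3, and 17, 24 and 25 without input naive 1, 2 and 3. The total of 2097 became 627 and 594 without IP naive 1 and 3, and 841 and 975 without input naive 2 and 3. With TMM factors 37.9% of called sites were higher in IP, with RLE factors 31.3% (613 up and 1345 down), and without factors 12.9% (229 and 1547). The median of all tested sites was -0.145, -0.222 and -0.41 under these scalings.

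In injured ganglia the same cell types were lower in IP. All called markers were lower: 10 satellite glia (median -1.76; adjusted p = 0.011 with an estimated correlation), 12 Schwann cell (-2.59; 0.00716), 6 macrophage (-2.68; 0.0316), 11 fibroblast (-3.11; 0.00552), 5 endothelial (-2.25; 0.00552), 4 pericyte (-2.23; 0.0164) and 3 erythroid genes (-3.42; 0.0164). In the planned test on sites, at the preset correlation, each of these lists passed (camera, highest adjusted p = 0.0383, for pericyte markers). With an estimated correlation on sites the adjusted p was 0.105, 0.0263, 0.0672, 0.0263, 0.0344, 0.0672 and 0.0344 in the same order. The satellite glia, macrophage and pericyte lists did not pass with that correlation. Pan-neuronal genes gave 8 higher and 0 lower (14 and 0 adjusted over the list alone; median 0.302; adjusted p = 0.021), nociceptor genes 3 and 0 (5 and 0 alone; 0.171; 0.0208), and regeneration genes 2 and 0 (adjusted p = 0.398). On sites each of these 3 lists had an adjusted p of 0.0344 with an estimated correlation. Proliferation genes passed at the preset correlation (adjusted p = 0.0203) and not with an estimated one (adjusted p = 0.122), and silencing genes did not pass (adjusted p = 0.579). Macrophage calls became 3 without IP injury 3 and 2 without input injury 2 or input injury 3, and pan-neuronal calls 2 and 4 without IP injury 1 and IP injury 3. Fibroblast calls became 7, 7 and 6 without IP injury 1, 2 and 3, endothelial calls 3 without IP injury 1, and pericyte calls 2 without IP injury 1, IP injury 2 or input injury 3. Nociceptor calls became 0 without IP injury 1. Regeneration calls became 0 without IP injury 1 and 1 without IP injury 3, input injury 1 or input injury 2. The largest falls of single sites were B2 copies in Gm34322 (chromosome 9, 61450326 to 61450351), at least 239-fold lower (adjusted p = 0.0201), and in Znrf3, a ubiquitin ligase gene (chromosome 11, 5401527 to 5401552), at least 80.2-fold lower (adjusted p = 0.016). A 3′ end site of Rpf2, a ribosome assembly gene (chromosome 10, 40223339 to 40223365), was at least 51.2-fold higher (adjusted p = 0.0172). Of the 6 sites named by rule, 5, 1 and 5 lost their call without IP injury 1, 2 and 3, and 1, 3 and 2 without input injury 1, 2 and 3. In all, 188 genes were higher and 462 lower, and 1333 sites were higher and 1202 lower. The 650 genes became 338 and 376 without IP injury 1 and 3. The 2535 sites became 466 and 634 without IP injury 1 and 3, and 1626, 1118 and 1093 without input injury 1, 2 and 3. With RLE factors 33.4% of called sites were higher (622 up and 1239 down) against 52.6% with TMM factors, and without factors 20.6% (326 and 1256). The median of all sites was -0.0993, -0.264 and -0.361 under TMM, RLE and no factors.

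Repeat families were compared because the table names a family for most sites. B2, a short interspersed element with its own RNA polymerase III promoter, took 9.78% ± 1.67 of the counts in naive input and 15.0% ± 1.39 in injured input (SD, n = 3), without overlap (exact permutation, two-sided p = 0.1, the smallest possible). In IP its share was 2.78% ± 1.1 in naive and 3.74% ± 1.69 in injured ganglia (exact permutation p = 0.5). With 1 library left out, this difference in percent of counts ranged from -0.0137 without IP injury 2 to 1.593 without IP naive 2. The fitted change of B2 after injury was 0.62 ± 0.36 in input (adjusted p = 0.626 by edgeR and 0.376 by DESeq2) and 0.46 ± 0.36 in IP (adjusted p = 0.893), with an interaction of -0.17 ± 0.51 (adjusted p = 0.955). B2 was lower in IP than in input, by -1.79 ± 0.37 in naive (adjusted p = 0.0167) and -1.96 ± 0.37 in injured ganglia (adjusted p = 0.00611), though not in every fit with 1 library left out in naive ganglia (highest adjusted p = 0.0657). Alu, which stands for B1 in the mouse, was lower in IP by -0.47 ± 0.10 (adjusted p = 0.013, highest 0.0568) and -0.50 ± 0.10 (adjusted p = 0.00494). The long interspersed element L1 was higher in IP from injured ganglia by 0.23 ± 0.05 (adjusted p = 0.00367, highest 0.0646), with shares of 1.14% ± 0.0238 and 1.01% ± 0.063, and not in naive ganglia (0.08 ± 0.05, adjusted p = 0.265). This excess depended on scaling. With the factors of the gene sums it was 0.03 (adjusted p = 0.799), and with B2 sites out of the total the L1 shares were 1.1888% ± 0.0279 in injured IP and 1.1836% ± 0.07 in injured input. Its interaction was 0.15 ± 0.06 (adjusted p = 0.661). CR1, an ancient element, was higher in IP from injured ganglia by 1.20 ± 0.21 (adjusted p = 0.0017) in every fit with 1 library left out, and from naive ganglia by 0.67 ± 0.21 (adjusted p = 0.043), a call kept only without input naive 2 (highest adjusted p = 0.175 without another library). Without its highest site CR1 was called in neither (adjusted p = 0.672 in naive and 0.239 in injured ganglia). The mixed family scRNA;Satellite was lower in naive ganglia by -3.62 ± 0.59 (adjusted p = 0.00235), also in every such fit, and in injured ganglia by -3.58 ± 0.59 (adjusted p = 0.00148). The DNA transposon family hAT-Charlie fell by 0.37 ± 0.06 after injury in input (adjusted p = 0.00975). It kept this call only without input naive 2 (highest adjusted p = 0.0959 without another library) and lost it with RLE factors, without factors and with DESeq2.

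For injury the families gave 0 calls in IP and 1 fall in input by edgeR, with 17 and 18 at an unadjusted p under 0.05. DESeq2 gave 1 rise and 2 rises, of families that edgeR did not call. In IP against input 12 families were higher and 17 lower in naive ganglia and 20 and 16 in injured ones, which became 2 and 15, and 8 and 20, with the factors of the gene sums. The interaction gave 0 of 180 (12 at an unadjusted p under 0.05, 0 by DESeq2). Of the 10 families named by rule in naive ganglia, among them RNA (-4.66 ± 1.09, adjusted p = 0.0167), 8, 7 and 9 lost their call without IP naive 1, 2 and 3, and 5, 4 and 7 without input naive 1, 2 and 3. Of the 6 in injured ganglia, among them srpRNA (-4.18 ± 1.12, adjusted p = 0.0325), 4, 3 and 5 did so without IP injury 1, 2 and 3, and 2, 2 and 3 without input injury 1, 2 and 3. At the level of single sites, 5 B2 copies were higher and 880 lower in IP from naive ganglia, of 13139 tested, and 5 higher and 871 lower in injured ones. After injury 46 B2 copies rose and 1 fell in IP, and 23 rose and 0 fell in input. Over all 46229 tested sites 145 rose and 5 fell in IP, and 83 rose and 13 fell in input. The share of sites that rose was thus similar for B2 copies and for all sites.

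**Figure D3:**
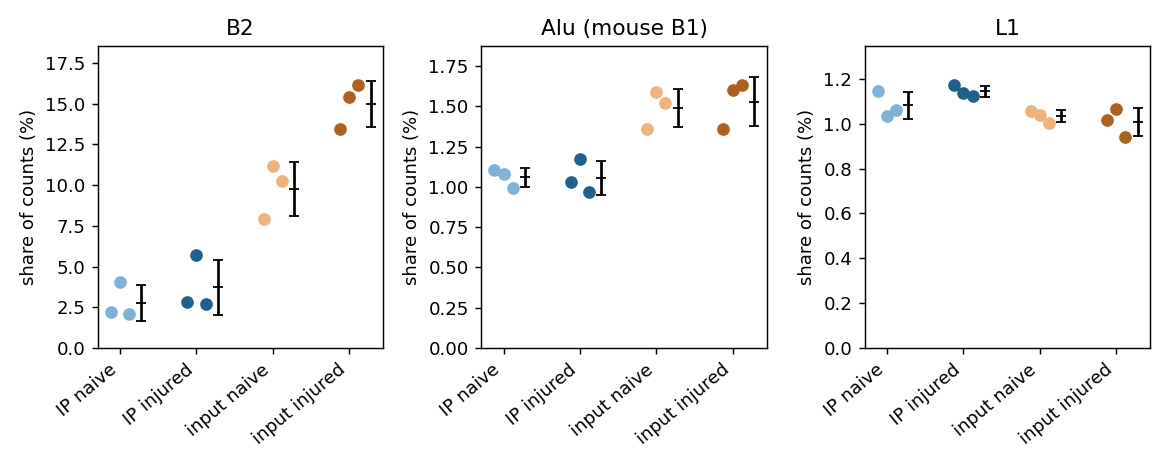
Share of all counts (%) at sites in B2, Alu (mouse B1) and L1 elements in each of the 12 libraries, with the mean and SD of each group of 3. The B2 share lies between 13.4% and 16.1% in injured input and between 7.93% and 11.2% in naive input.

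The series concerns alternative polyadenylation, so the use of single 3′ end sites within a gene was compared. Mbp, which encodes myelin basic protein, had a site 26980 bp upstream of its annotated 3′ end (chromosome 18, 82558645 to 82558670, GRCm38) that took 14.5% ± 6.25 of the gene's counts in naive IP and 1.80% ± 0.473 in naive input (gene adjusted p = 0.00252, diffSpliceDGE of edgeR). In injured ganglia the shares were 11% ± 5.03 and 1.21% ± 0.0393 (adjusted p = 0.00165). Ntrk2, the gene of the BDNF receptor TrkB, had a pair of sites in the middle of the gene with a smaller share in IP. At 58932411 to 58932436 on chromosome 13, 201547 bp upstream of the 3′ end, the share was 2.16% ± 1.19 in naive IP and 14.0% ± 0.942 in naive input. At 58936986 to 58937011 it was 7.70% ± 1.24 and 22.8% ± 4.31 (gene adjusted p = 0.00315), and 8.44% ± 2.00 and 30.9% ± 5.39 in injured ganglia (adjusted p = 0.0169). Sptbn1, which encodes a spectrin, used a site 7480 bp upstream (chromosome 11, 30106859 to 30106891) for 4.15% ± 1.36 of its counts in naive IP and 14.1% ± 2.52 in naive input (adjusted p = 0.00587), and for 8.99% ± 2.67 and 13.3% ± 1.06 in injured ganglia, where it was not called. The calmodulin gene Calm3 used a site 1451 bp upstream (chromosome 7, 16916814 to 16916847) for 1.49% ± 0.378 and 6.36% ± 1.62 (adjusted p = 0.0103), and in injured ganglia, again without a call, for 2.47% ± 0.247 and 6.39% ± 2.25. Alox5ap, a leukotriene synthesis gene of leukocytes, used one of its sites (chromosome 5, 149288102 to 149288127) for 1.34% ± 1.29 and 65.6% ± 22.3 (adjusted p = 0.0139), but for 61.4% ± 21 and 63.8% ± 9.67 in injured ganglia. The Zmiz1 site given above held 11.6% ± 6.03 of the counts in naive IP and 0 in naive input (adjusted p = 0.0403), and 2.11% ± 0.827 in injured IP and 5.07% ± 2.86 in injured input, where it was not called.

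These 6 genes were the ones called between IP and input in naive ganglia, of 5340 tested. Mbp and Ntrk2 were the 2 called in injured ganglia. Because IP and input differ in their mix of cells, a share can differ when other cells use another 3′ end, without a change within neurons. Mbp and Alox5ap are genes of myelinating cells and leukocytes, and their RNA in IP may be carried over from input. Neither was tested. The count in naive ganglia became 0, 10 and 1 without IP naive 1, 2 and 3 (smallest adjusted p = 0.0571 in the first case), and 4 and 2 without input naive 2 and 3. In injured ganglia it became 1 without IP injury 1 or 3 and 0 without input injury 1 (smallest adjusted p = 0.0523). After injury 0 genes were called for a changed use of sites in IP and 0 in input by edgeR. At an unadjusted p under 0.05 there were 124 and 228, and no second tool was run. The smallest adjusted p was 0.176 in IP, for Alox5ap, and 0.881 in input. In simulated data for injury in IP, 0%, 10.4% and 45.5% of changed sites of 2-fold, 4-fold and 16-fold were recovered. For injury in input 1.49%, 5.97% and 34.8% were recovered. Most shifts, those of 16-fold included, were thus missed with these libraries, and the absence of calls does not exclude large shifts. With all sites in repeats included, 9, 3, 119 and 43 genes were called for injury in IP, injury in input, and IP against input in naive and injured ganglia.

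**Figure D4:**
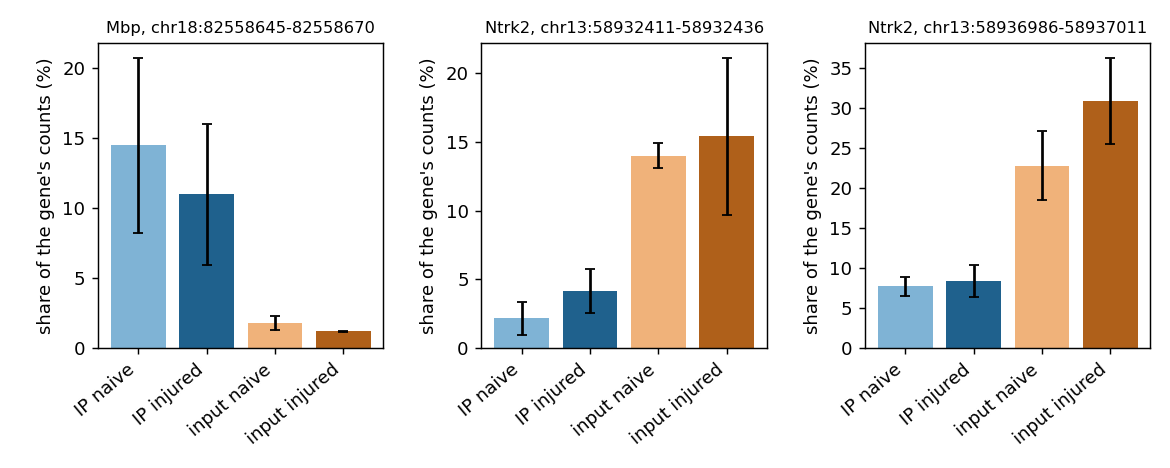
Share of the gene's counts (%) at 1 site of Mbp and 2 sites of Ntrk2 in the 4 groups (bars, mean; whiskers, SD, n = 3). The Mbp site took 14.5% in naive IP and 1.80% in naive input, and the Ntrk2 sites were lower in IP.

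Sites at annotated 3′ ends held 54.6% ± 0.829 of the counts in naive IP and 50.6% ± 1.00 in naive input, and 55.5% ± 0.821 and 48.6% ± 1.52 in injured ganglia (SD, n = 3; exact permutation, two-sided p = 0.1 in both, without overlap, which chance gives in 10% of splits). Most of this difference went with B2: with B2 sites out of the total the shares were 56.0533% ± 1.2639 and 55.8988% ± 0.1226 in naive and 57.5094% ± 0.7908 and 56.9696% ± 0.87 in injured ganglia (exact permutation p = 0.8 and 0.3). Sites outside genes held 14.0% ± 1.28 in injured IP and 18.9% ± 2.12 in injured input (exact permutation p = 0.1), and 15.7% ± 1.955 and 18.3% ± 1.299 in naive ganglia, with overlap (exact permutation p = 0.3). Without ribosomal RNA sites the shares were 4.68% ± 0.838 and 10.8% ± 0.976 in injured and 4.18% ± 0.457 and 8.10% ± 0.905 in naive ganglia (exact permutation p = 0.1 in both). Without B2 sites they were 12.7% ± 1.779 and 13.9% ± 1.881 in injured ganglia (exact permutation p = 0.5). In input, the share on the opposite or an unresolved strand of a gene was 3.52% ± 0.379 in naive and 4.69% ± 0.321 in injured ganglia (exact permutation p = 0.1). Of 11293 tested sites at annotated 3′ ends, 446 were higher and 218 lower in IP from naive ganglia, against 25 and 482 of 10075 sites outside genes. Without factors 115 were higher and 298 lower at annotated 3′ ends, and 11 and 547 outside genes.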

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

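For the B2 rise, the tests of host genes, of ribosomal RNA, of priming and of a lower neuronal share, and for B2 in the IP the test of carry-over, were chosen only after the result was seen. The test of a few B2 sites and both tests of the IP libraries numbered 2 were not, but the way 2 tests were read, that of priming and that of carry-over into the libraries numbered 2, was changed after their values were seen, as stated below.

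A pair of differences between IP and input drew attention because the injury effect itself was tested to differ. At the level of single sites, the regeneration list rose more in IP than in input (camera at the preset correlation, adjusted p = 0.042), and B2 sites rose less (adjusted p = 0.00856). With an estimated correlation the adjusted p was 0.999 and 0.601, so neither held. Of 40 drawn splits of the libraries, out of 200 possible, 34 gave as many lists as the real one (1, with a highest of 4). As many families as the real one (1, with a highest of 13) came from 35, so chance is not excluded. Some draws kept the real IP groups and regrouped input alone, so they hold part of the real effect and are no pure measure of chance. Splits that called 13 families where the real one called 1 point to a structure of the samples or to correlation between the sites of a set, and no test separated them.

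The B2 share of counts in input was 9.78% ± 1.67 in naive and 15.0% ± 1.39 in injured ganglia, although the fitted change of the family did not pass the threshold (adjusted p = 0.626, edgeR). A smaller share of ribosomal RNA was argued against by a ratio of injured over naive input of 1.5 with ribosomal RNA out of the total. The ratio was 1.64 without the 100 most abundant B2 sites (11.9% ± 1.21 and 7.25% ± 1.26). For sites outside genes it was 1.57 (7.07% ± 0.737 and 4.5% ± 0.791). Both met the bounds set against a few abundant copies and transcripts of host genes, which assume that each read lay at its own copy. How reads with several alignments were treated is not stated. Transcripts that ran more than 200 bp past an annotated 3′ end also counted as outside genes. Neither explanation is therefore excluded. A lower share of neuronal RNA would raise the markers of every other cell type alike, if injury did not change those markers itself. They moved apart in input. The median log2 change was 0.938 for macrophage, 0.286 for fibroblast, 0.136 for pericyte, 0.0976 for Schwann cell, 0.0274 for endothelial, 0.0258 for erythroid and -0.198 for satellite glia markers. The upper quartile of Schwann cell markers, 0.155, met the bound set against this explanation. That quartile is of single genes and no spread of the median, and whether injury changes the markers was not tested. A lower neuronal share is therefore not excluded. Priming on A-rich stretches of genomic DNA or unspliced RNA would also raise other repeats that end in such stretches. The summed share of Alu, L1, ID and B4 sites outside genes had a ratio of 1.04 ± 0.0552 against 1.57 ± 0.322 for B2. Singly the ratios were 1.02 ± 0.0623 for L1, 0.799 ± 0.265 for ID and 0.793 ± 0.109 for B4, while that for Alu, 1.1 ± 0.187, overlapped the spread of B2. The bound of this test was changed 2 times after values were seen. An Alu ratio below 1.3 by more than 1 SD was met and counted against priming. It was replaced by an Alu ratio below that of B2 by more than both spreads, which was not met. The last bound, the same on the sum of the 4 families, was met. A bound chosen after the values were seen cannot decide, so priming is not excluded. The injury itself and RNA of macrophages may also raise the B2 share, and neither was tested.

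B2 RNA was present in IP, at 2.78% of the counts in naive and 3.74% in injured ganglia. A candidate explanation is RNA of the input carried into the IP. The ratio of IP over input for B2 sites outside genes lay above the upper quartile of the ratios of 104 marker genes of other cells in 1 of 6 IP libraries, IP naive 2 (0.405 against 0.373). It lay above the median of the markers in 5 of 6, for example 0.228 against 0.0829 in IP naive 1, and below it in IP injury 3 (0.175 against 0.22). The quartiles are of single genes, which differ widely, and so are no spread of the median. Carry-over therefore cannot be told apart from B2 RNA on the ribosomes of neurons, which was not tested.

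The IP libraries numbered 2 lay nearer to input than the other IP libraries. Their correlation with the mean of the input across sites was 0.9002 in naive and 0.8797 in injured ganglia, and each was the highest of its group. Lower depth was argued against: with all IP libraries thinned to 10045178 counts, library 2 stayed the highest in 2 of 2 conditions (0.8995 and 0.8789). More RNA of the input carried into these libraries could also explain it, and library 2 had the highest median marker ratio in 1 of 2 conditions (0.192 in naive IP, but 0.209 against 0.22 of IP injury 3), with a median log2 difference to the other libraries of 0.452 and 0.431 across 104 markers. The bound written in advance, that library 2 was not the highest in at least 1 condition, was met and by itself would have counted against carry-over. It was met by less than its spread: in injured ganglia the median ratio of library 2 minus that of IP injury 3 was -0.0111 ± 0.0257 (SD over 2000 redrawn sets of markers). This spread and the marker differences, whose quartiles in injured ganglia were -0.198 and 0.873, were added after that result. Carry-over cannot be told apart from a difference between the pools, which the labels do not name.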

How the results depend on the processing

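Alternatives on gene sums, on the use of sites and on lists summed per gene, the fits without both IP libraries numbered 2, the factors of the gene sums, the site fits without ribosomal RNA sites, and the shares without ribosomal RNA, without B2 or with a library left out were chosen after seeing the data. The others were not. Of the counts and shares that answer a comparison, 457 values stayed within 1.5 times the reported count or, for shares, within their spread. Of the others, 53 counts moved up, 87 moved down, 15 shares moved by more than their spread, and 0 shares reversed. Counts were compared by their totals alone, so a change in the balance of rises and falls was not scored. For IP against input in injured ganglia, 1333 sites were higher and 1202 lower, but 622 and 1239 with RLE factors. A share was counted as reversed only where its groups did not overlap with all sites. Of 2961 values for 196 named sites, genes and families, 2226 kept direction and call, 710 kept their direction and lost the call, and 25 reversed. The alternative restricted to sites that overlap no exon was not run, because the gene table holds no exons. Unless stated, the cause was not tested.

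Counts below are in the order injury in IP, injury in input, IP against input in naive, IP against input in injured, and interaction. For sites, DESeq2 called 975, 863, 6284, 5799 and 77, and dropping the filter gave 756, 490, 3523, 4046 and 32. Without factors, 1582 sites were called for IP against input in injured ganglia. Fitting only the groups compared, with fewer libraries to estimate the spread, gave 81 sites for injury in IP and 657 for IP against input in naive ganglia. Without both IP libraries numbered 2, injury in IP gave 234 sites. For genes, DESeq2 called 359, 285, 1282, 1038 and 13. Only the groups compared gave 281 genes in IP and 92 in input, and only sites at annotated 3′ ends gave 92 for injury in input and 511 for IP against input in naive ganglia. The term for the replicate number gave 122, 123, 2523, 3031 and 0 sites, and 240, 209, 1044, 886 and 0 genes, all within 1.5 times the reported counts.

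For the use of sites, including all sites in repeats gave 9, 3, 119 and 43 genes. Leaving out both IP libraries numbered 2 gave 1 for injury in IP and 10 for IP against input in naive ganglia. For families after injury in input, the 1 call became 0 with RLE factors, without factors, without the filter, without the highest site, for sites outside genes and with the factors of the gene sums, 2 with DESeq2 and 4 with the replicate term. For families after injury in IP, the count of 0 became 1 with DESeq2, with only the groups compared, without both IP libraries numbered 2 and for sites outside genes, and 2 without the highest site. For IP against input in naive ganglia, families dropped to 15 without the filter, 16 with only the groups compared, 19 without the highest site, 11 for sites outside genes and 17 with the factors of the gene sums, of which 2 were higher and 15 lower in IP. In injured ganglia they dropped to 20 for sites outside genes.

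With an estimated correlation, the lists tested on sites dropped to 1 for injury in IP, 1 for injury in input, 5 for IP against input in naive ganglia and 0 for the interaction, and the families tested as sets to 0, 0, 2 and 0 in the same order. Without both IP libraries numbered 2, the lists for injury in IP dropped to 1, the family sets became 3 for injury in IP and 2 for the interaction, and lists summed per gene became 1 for the interaction.

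With 1 library left out, sites ranged from 66 to 332 for injury in IP, from 45 to 69 for injury in input, from 594 to 2970 and from 466 to 2683 for IP against input in naive and injured ganglia, and from 0 to 1 for the interaction. Genes ranged from 99 to 195, 99 to 130, 495 to 879, 338 to 550 and 0 to 2 in the same order. Families ranged from 0 to 1, 0 to 1, 5 to 23 and 17 to 33, with 0 for the interaction in each fit, and genes with a changed use of sites from 0 to 1, 0 to 1, 0 to 10 and 0 to 2. Lists tested on sites ranged from 1 to 4 for injury in IP, 2 to 4 for injury in input and 0 to 1 for the interaction. Lists summed per gene ranged from 2 to 6 for injury in IP and 0 to 1 for the interaction, and families tested as sets from 1 to 6, 4 to 7 and 0 to 3 for injury in IP, injury in input and the interaction. In percent of counts, the difference in the share at annotated 3′ ends became 5.27 for IP against input in naive ganglia and -0.679 for injury in IP without ribosomal RNA, and -0.453 for injury in IP and -3.51 for injury in input without the 10 most abundant sites. The difference in the share outside genes became 0.504 for injury in IP without ribosomal RNA. With B2 sites out of the total, which removes the dilution of the other shares by B2, the difference at annotated 3′ ends became 1.0709 for injury in input, the other direction than -1.9757 with all sites, 0.1545 for IP against input in naive and 0.5398 in injured ganglia. Outside genes it became -0.4001 and -1.238 for IP against input in naive and injured ganglia. For L1 it became 0.0368 for injury in input, and -0.0348 and 0.0052 for IP against input in naive and injured ganglia, and for Alu -0.5631 and -0.7021 in the latter 2.

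Reversals concerned families whose change was near 0, except a mixed class. The family named Low_complexity,Simple_repeat went to 0 in naive and -3.61 in injured ganglia without its highest site. Alu after injury in IP went to -0.00366 without factors, -0.0061 with the filter of 30 counts, -0.0494 without both IP libraries numbered 2, -0.00783 without the highest site and -0.0105 with the factors of the gene sums, and ranged from -0.0658 to 0.158 with 1 library left out. After injury in input Alu ranged from -0.0342 to 0.183. L1 after injury in input went to 0.0175 with RLE factors, 0.0176 with DESeq2, 0.00603 without the filter, 0.0135 with only the groups compared, 0.00839 outside genes and 0.0633 with the factors of the gene sums, and ranged from -0.0509 to 0.0189 with 1 library left out. L1 for IP against input in naive ganglia went to -0.0291 without the filter. The interaction ranged from -0.127 to 0.0642 for Alu and from -0.635 to 0.216 for B2 with 1 library left out. What depth limits was not separated from the number of libraries and of tests: on simulated data for injury in IP, made at the depth of these libraries only, 2-fold changes were found at 2.99% of sites and 37.3% of genes.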

Other observations

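The genes in the first paragraph of this part and all tests with gene sums and the use of sites were chosen after the data had been seen. The tests on other splits were not.

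Of the 81 genes that rose after injury in both IP and input, 53 were called in every fit with 1 library left out, and 28 of the 81 were on one of the lists. Outside the lists, Car3, a carbonic anhydrase gene, rose by 3.45 ± 0.25 on the log2 scale in IP and 2.98 ± 0.25 in input, with an adjusted p of at most 9.4e-06 in any fit without 1 library (edgeR). Plin2, which coats lipid droplets, rose by 2.18 ± 0.17 and 1.92 ± 0.17 (at most 1.48e-05), the secreted neuropeptide precursor gene Vgf by 1.83 ± 0.16 and 1.84 ± 0.16 (1.48e-05), and the antioxidant gene Srxn1 by 1.28 ± 0.11 and 1.37 ± 0.11 (6.89e-06). Phlda1 rose by 2.15 ± 0.22 and 2.18 ± 0.22 (7.77e-05), the small GTPase gene Rhoc by 1.85 ± 0.17 and 1.38 ± 0.17 (0.000529), and the lysosomal membrane gene Cd63 by 1.92 ± 0.16 and 1.17 ± 0.15 (0.00151). The tubulin genes Tuba1c and Tubb2b rose by 2.19 ± 0.20 and 1.81 ± 0.20 (0.000239) and by 0.83 ± 0.12 and 1.07 ± 0.12 (0.00404). Slc6a4, the serotonin transporter gene, rose by 6.44 ± 1.01 and 6.94 ± 1.07 (0.0204), from 13 counts in naive IP and 7 in naive input to 1249 and 865. Of the 11 genes that fell in both, Etv1 alone was called in every such fit (-0.95 ± 0.16 in IP and -1.01 ± 0.17 in input, at most 0.023).

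Other splits of the same libraries were fitted in the same way. With 3 against 3 libraries there are 10 splits, too few for a share under 0.05. Every other split mixed the real groups, so that a real difference entered the spread within groups and lowered the calls. Low counts of sites and genes in the other splits are therefore no measure of false calls. In the order injury in IP, injury in input, IP against input in naive and in injured ganglia, the real split called 150, 96, 2097 and 2535 sites, and the highest other split 3, 0, 4 and 0. It called 170, 143, 800 and 650 genes against 9, 6, 1 and 0, and in each of these cases 1 split of 10, the real one, reached the real count. For families it called 0, 1, 29 and 36 against 0, 1, 0 and 0, reached by 10, 2, 1 and 1 splits, and for the use of sites 0, 0, 6 and 2 against 1, 2, 0 and 0, reached by 10, 10, 1 and 1. Lists tested on sites gave 3, 4, 10 and 10 against 6, 2, 7 and 9, reached by 4, 1, 1 and 1 splits, and families tested as sets gave 5, 8, 13 and 15 against 9, 6, 9 and 15, reached by 5, 1, 1 and 2. For the interaction the real count was 0 sites, 0 genes and 0 families, which any split reaches (40 of 40 drawn, with highest others of 1, 3 and 1), so the splits decide nothing there.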
